A study of Homo sapiens with 6 samples.

How the data were processed

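Chromatin occupancy of the SWI/SNF chromatin remodelling complex was profiled by ChIP-seq in 2 prostate cancer cell lines with 2 antibodies. The antibodies recognised BRG1, the ATPase encoded by SMARCA4, and SMARCC2, a core scaffold subunit also called BAF170. Per the labels' protocols, cells were fixed with 2 mM disuccinimidyl glutarate (DSG) for 45 min and then with 1% formaldehyde for 10 min, chromatin was sonicated, and 4 µg of antibody was used per precipitation. MR49F cells were grown with 10 µM enzalutamide, and no enzalutamide is given for LNCaP, so line and drug exposure cannot be separated. The series holds 6 samples: 1 library per line and antibody, and 1 input per line. Each of the 4 precipitated libraries has a peak list, and the 2 inputs were not analysed here.

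The submitters' processing notes name BWA 0.7.10, SAMtools and MACS2 2.1.0, and the genome build hg38. They give no role or order for the tools. Which input served as control, how duplicates were treated and how reads were filtered are not given in the sources used here. Each deposited peak list comes from 1 library, so no pooling of replicates took place. Each deposited peak carries a fold enrichment over local background and a −log10 p-value and −log10 q-value, as the authors' peak caller wrote them. A deposited display score equals the whole part of 10 times the −log10 q-value for 99.89% to 99.99% of the peaks of a list, and was not used further. The lowest −log10 q-value in the deposited lists lies between 2.001 and 2.014, which corresponds to a q-value threshold of 0.01. Fold, p-value and q-value per peak are the authors' own and were used to describe, rank or filter peaks within a list. Fold and p-value also served to estimate depth and local background, which were compared between lines.

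Peaks of different lists that shared at least 1 bp were joined into regions, and a region was classed by the lists with a peak in it. Overlaps were computed with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1 under Python 3.11.15, in place of the bedtools named beforehand, and plots were drawn with matplotlib 3.10.9. Shares are given with Wilson 95% intervals, which cover counting error only. The number of overlapping peaks was set beside the mean of 100 placements of the list at uniform positions within its chromosomes, up to the last position seen in the lists or the gene table. Uniform placement ignores mappability and open chromatin, so it is a low reference. A missing peak means that the caller's threshold was not reached, not that the protein was absent.

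With 1 library per line and antibody there was no replicate, so no difference between lines has a replicate check and no p-value was computed. Regions called with both antibodies in the same line are the nearest thing to a repeat in this design. The libraries of a line may share an input, and artefacts of that input would then appear with both antibodies. Local background could then also come from the same input with both antibodies.

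Genes were taken from a table of RefSeq genes on assembly GRCh38.p14, the same build as hg38, with 20037 protein-coding genes. It gives gene spans without strand, and no genome sequence was used here. The plan to use transcription start sites was therefore changed to the nearer end of a gene, whichever of its ends that is. A peak summit or region midpoint was assigned to the protein-coding gene with the nearest end within 100 kb. This assigned between 77.7% (MR49F SMARCC2) and 82.4% (LNCaP BRG1) of peaks. Location was classed as gene end (midpoint within 1 kb of an end of a protein-coding gene), gene span (elsewhere inside such a gene) or between genes. Exons, introns and promoters were not separated. The planned search for 18 transcription factor motifs at summits needs genome sequence and was not run.

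The 18 gene lists were fixed before the data were examined, and 336 of their 337 entries matched a protein-coding gene. They cover androgen response, luminal prostate, basal and stem-like, neuroendocrine, mesenchymal, AP-1 factors, YAP and TEAD pathway, Wnt pathway, glucocorticoid receptor and its targets, steroid metabolism, SWI/SNF subunits, cell cycle and MYC, interferon and inflammatory signalling, receptor kinases and survival signalling, housekeeping, fibroblast, leukocyte, and hepatocyte and muscle genes. For each list and antibody, the MR49F share was the number of MR49F peaks divided by the sum of MR49F and LNCaP peaks at its genes. Its percentile was taken among 10000 random lists of the same size matched on peaks per gene. A list was counted as high or low when it lay in the top or bottom 2.5% with both antibodies. These percentiles describe these libraries and are not p-values.

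Named genes followed a rule set before the data were examined. They were the 8 genes with the most regions called by both antibodies in MR49F and by neither in LNCaP, and the 8 with the most of the reverse. Added to them were up to 2 genes per list and direction with at least 1 such region, the genes at the 5 strongest such regions of each direction, and a few fixed genes, among them SMARCA4, SMARCC2, KLK3, FKBP5 and TMPRSS2. Some genes that the rule names are not reported here. Strength was ranked by the lower of the 2 antibodies' −log10 q-values.

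Depth, given in megatags (M tags), is not stated in the labels. It was estimated from each list by solving the caller's formula for fold and p-value for the tag pileup and local background of each peak with a −log10 p-value below 100. A solution was kept when the pileup lay within 0.02 of a whole number of tags, which held for 97.9% to 99.9% of those peaks. The lowest background gives the number of tags, if the caller used its default human genome size of 2.7 Gb, which the labels do not state. Ratios of depths do not need that size. Both LNCaP libraries came out as scaled down to the same 24.5 M tags, which a shared input would give. The MR49F lists gave no sign of this either way. The overlap step was tested on 20000 simulated sites and recovered 8000 of 8000 shared sites. These sites lay apart from each other and were shifted little, so the joining of clustered or wide peaks was not tested. The list step, tested on 2000 simulated genes, recovered 9 of 10 raised lists and called 0 of 10 unchanged lists. It did not cover the rule that asks for both antibodies.

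Alternatives fixed beforehand were a reciprocal overlap of 50%, summits within 200 bp, peaks with a −log10 q-value of 5 or more in every list or in the counted line only, the 10000 strongest peaks of each list, chromosomes 1 to 22 only, gene ends widened to 2.5 kb, and assignment within 10 kb or to every gene span extended by 10 kb. Leaving out list genes on chromosome X was added after seeing the data.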

Results

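BRG1 and SMARCC2 peaks were compared between LNCaP, a human prostate adenocarcinoma line that responds to enzalutamide, and MR49F, an enzalutamide-resistant derivative of LNCaP. Enzalutamide is an antiandrogen drug. BRG1 and SMARCC2 belong to SWI/SNF, a complex that moves nucleosomes and opens chromatin. The series title concerns the dependence of resistant cells on this complex, and the comparisons ask where the subunits sit in each line. There was 1 library per line and antibody and thus no replicate error for any value below. The number of peaks was 36174 for LNCaP BRG1, 25706 for LNCaP SMARCC2, 44308 for MR49F BRG1 and 47615 for MR49F SMARCC2. Median peak widths were 743, 659, 820 and 753 bp, and the peaks covered 34.28, 20.35, 47.27 and 44.75 Mb in the same order. Depth, solved from the peak statistics, was about 25.2 M tags for LNCaP BRG1 and 26.6 M for LNCaP SMARCC2. It was about 20.4 M for MR49F BRG1 and 18.5 M for MR49F SMARCC2, so the MR49F libraries had more peaks from fewer tags.

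BRG1 was called at a larger set of regions in MR49F than in LNCaP. Of 55512 BRG1 regions, 23082 were called in both lines, 20591 in MR49F only and 11839 in LNCaP only. MR49F BRG1 peaks were found at 67.3% of LNCaP BRG1 peaks (Wilson 95% interval 66.8 to 67.8). LNCaP BRG1 peaks were found at 53.5% of MR49F BRG1 peaks (53.1 to 54.0). Uniform placement gave 3.04% and 2.47%. Regions in both lines had a median width of 1317 bp, against 648 bp for those in MR49F only and 579 bp for those in LNCaP only. Among the strongest 10% of LNCaP BRG1 peaks, 6.97% (6.18 to 7.84) had no MR49F peak, and in the weakest 10% 51.9% had none. In MR49F, 19.8% (18.6 to 21) of the strongest 10% and 70.1% of the weakest 10% of BRG1 peaks had no LNCaP peak. The ratio of MR49F to LNCaP BRG1 peaks was 1.22. When each list was limited to its 10000 strongest peaks, 5629 regions were in MR49F only and 5569 in LNCaP only, a balance that equal list lengths largely impose.

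The difference between lines was wider for SMARCC2. MR49F held 1.85 times as many SMARCC2 peaks as LNCaP. Of 53289 SMARCC2 regions, 28287 were called in MR49F only, 19126 in both lines and 5876 in LNCaP only. MR49F peaks were found at 77.1% (76.6 to 77.7) of LNCaP SMARCC2 peaks, whereas LNCaP peaks were found at 40.6% (40.2 to 41.0) of MR49F SMARCC2 peaks, with 2.76% and 1.49% under uniform placement. In the strongest 10% of the LNCaP list 3.77% (3.1 to 4.58) of SMARCC2 peaks had no MR49F peak. In the strongest 10% of the MR49F list 26.1% (24.9 to 27.3) had no LNCaP peak. With the 10000 strongest peaks of each list, 5401 SMARCC2 regions were in MR49F only and 5336 in LNCaP only.

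**Figure D1:**
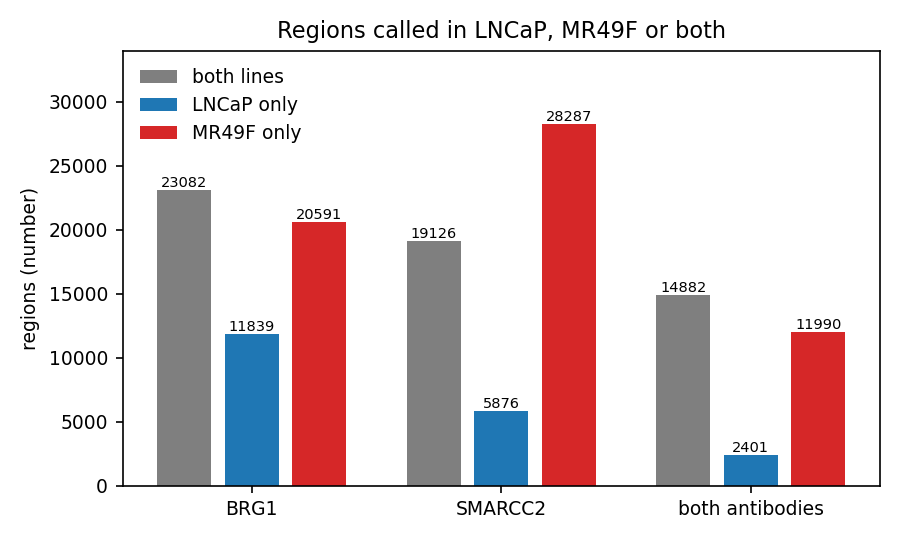
Bars give the number of regions (y axis) called in both lines, in LNCaP only or in MR49F only, for BRG1, for SMARCC2 and for regions called with both antibodies (for these, grey is the 14882 regions in all 4 lists). MR49F-only regions outnumber LNCaP-only regions in each group, by 20591 to 11839 for BRG1, 28287 to 5876 for SMARCC2 and 11990 to 2401 for both antibodies.

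Within a line, most peaks of each list overlapped a peak of the other antibody when any overlap was counted. For LNCaP BRG1 peaks this no longer held with reciprocal overlap or with matching by summits, as given below. In LNCaP, 80.1% of SMARCC2 peaks (79.6 to 80.6) overlapped a BRG1 peak and 55.3% of BRG1 peaks (54.8 to 55.8) overlapped a SMARCC2 peak. In MR49F, 75.7% of SMARCC2 peaks (75.4 to 76.1) overlapped a BRG1 peak and 79.8% of BRG1 peaks (79.4 to 80.1) overlapped a SMARCC2 peak. Uniform placement gave between 1.55% and 3.19%. The strongest 10% of BRG1 peaks carried SMARCC2 at 97.1% of sites in LNCaP, and all but 2 of 4431 did so in MR49F. In the weakest 10%, SMARCC2 was found at 23.2% of LNCaP and 38.5% of MR49F BRG1 peaks.

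**Figure D2:**
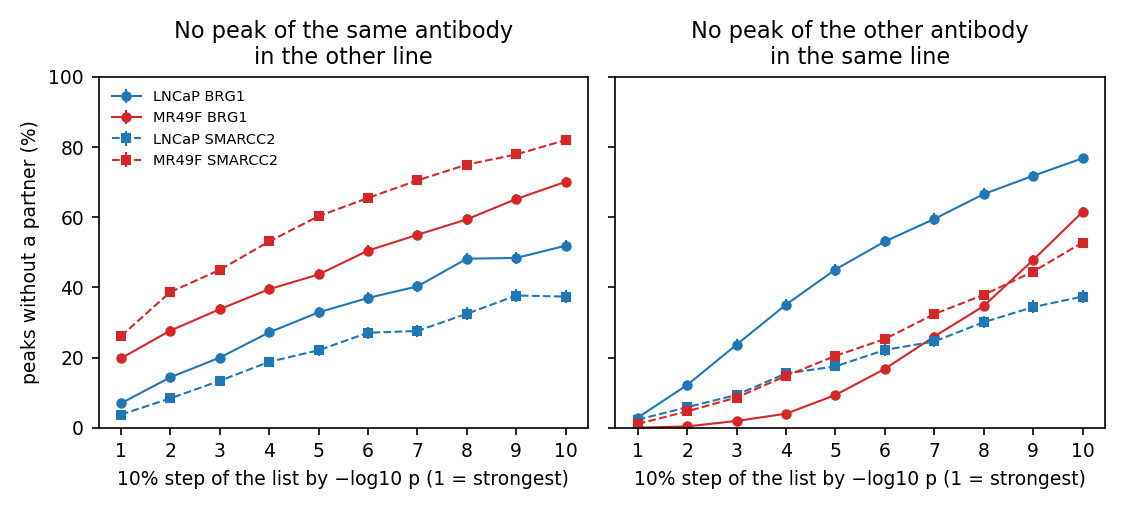
Points give the percent of peaks without a partner (y axis) in each 10% step of a list ranked by −log10 p-value (x axis, 1 is the strongest), with Wilson 95% intervals as bars; LNCaP is blue, MR49F red, BRG1 circles with solid lines and SMARCC2 squares with dashed lines. In the left panel, 26.1% of the strongest and 82.0% of the weakest MR49F SMARCC2 peaks lack a LNCaP SMARCC2 peak; in the right panel, 76.8% of the weakest LNCaP BRG1 peaks lack a SMARCC2 peak in the same line.

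Regions that both antibodies called in a single line showed the same imbalance. They come from the same 4 lists, whose unequal lengths also shape this count. Merging all 4 lists gave 65483 regions, of which 14882 (22.7%) had a peak in every list. Both antibodies called 11990 regions (18.3%) in MR49F with no peak in LNCaP, and 2401 (3.67%) in LNCaP with no peak in MR49F. Among the 40576 regions that each antibody called in some line, 84.3% of the MR49F-only BRG1 regions were also MR49F-only for SMARCC2, and 48.8% of the LNCaP-only BRG1 regions were also LNCaP-only for SMARCC2. The observed number was 1.82 times that under independence for MR49F-only regions and 5.61 times for LNCaP-only regions. These 2 ratios have different upper limits, set by the numbers of regions, and do not rank the agreement of the classes. With the 10000 strongest peaks of each list, the counts were 2876 in MR49F only and 2294 in LNCaP only, a setting that moves the counts towards balance by its construction.

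The strongest MR49F-only region lay on chromosome 12 from 46792614 to 46793695 (hg38), inside SLC38A4, which encodes an amino acid transporter. Its −log10 q-value was 161 for BRG1 and 523 for SMARCC2, and SLC38A4 had 4 MR49F-only regions and 0 peaks in LNCaP. The next were on chromosome 9 from 65661575 to 65663933 inside ZNG1E, and on chromosome 9 from 80749308 to 80750226 with no protein-coding gene end within 100 kb. ZNG1E belongs to a family of near-identical gene copies, among which reads cannot always be placed. The remaining MR49F-only regions of this group were on chromosome 9 from 110078105 to 110079681 inside PALM2AKAP2, and on chromosome 7 from 138095975 to 138097710 inside AKR1D1, the steroid 5-beta-reductase gene. The 5 MR49F-only regions had BRG1 −log10 q-values from 152 to 161. Among LNCaP-only regions the strongest was on chromosome 7 from 112267981 to 112268902 inside ZNF277, with −log10 q-values of 47.4 for BRG1 and 81.2 for SMARCC2, and ZNF277 had 3 MR49F-only regions beside this 1 LNCaP-only region. The next were a region on chromosome 6 from 130007668 to 130008797, which lay 10.3 kb from L3MBTL3, and a region on chromosome 3 from 174972868 to 174974220, inside NAALADL2. The others were on chromosome 8 from 131882681 to 131883372, at 21.1 kb from EFR3A, which also had 2 MR49F-only regions, and on chromosome 3 from 149906376 to 149907594 inside RNF13. In the 10 Mb windows of the LNCaP-only regions, the ratio of MR49F to LNCaP background was 0.78 to 0.893 for L3MBTL3, NAALADL2 and RNF13. It was 1.04 to 1.09 for ZNF277 and EFR3A. For the MR49F-only regions it was 1.15 with BRG1 and 1.26 with SMARCC2 at SLC38A4, 0.91 and 0.835 at ZNG1E, and 1.02 to 1.15 for the others.

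At the level of genes, 5352 of 20037 protein-coding genes had more MR49F than LNCaP peaks with both antibodies, and 756 had more LNCaP peaks with both. At least 1 MR49F-only region of both antibodies was assigned to 6272 genes, at least 1 LNCaP-only region to 1567, and both kinds to 683. KDM6A, a histone H3 lysine demethylase gene on chromosome X, had the most MR49F-only regions, 12, beside 12 regions in all 4 lists. Local background on chromosome X, relative to autosomes, was 1.33 times higher in MR49F than in LNCaP with BRG1 and 1.35 times with SMARCC2. IGF1R, which encodes the insulin-like growth factor receptor, had 9 MR49F-only regions. RND3, a small GTPase gene, had 8, and its LNCaP lists held 0 peaks against 9 BRG1 and 12 SMARCC2 peaks in MR49F. STXBP5 also had 8. CAPZB, an actin capping protein gene, CRIM1 and GRB10, an adaptor of the insulin and insulin-like growth factor receptors, had 7 each. These 7 genes had 0 LNCaP-only regions. In the 10 Mb windows that hold them, the ratio of MR49F to LNCaP background was 1.54 with both antibodies around KDM6A and between 0.814 and 1.22 around the other genes. With the 10000 strongest peaks of each list, the MR49F-only minus LNCaP-only count came to 0 for IGF1R and CRIM1, 1 for RND3 and STXBP5, and 4 for KDM6A. With assignment within 10 kb it came to 0 for CAPZB, CRIM1 and GRB10. With gene spans extended by 10 kb, IGF1R had 17 MR49F-only regions and KDM6A 15, so the order of these 2 genes turned.

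LNCaP-only regions were most frequent at TBL1XR1, which encodes a subunit of corepressor complexes, with 8 regions and 39 BRG1 peaks in LNCaP against 20 in MR49F. PPP3CA, the gene of a calcineurin catalytic subunit, had 7, and ATP2C2, a calcium-transporting ATPase gene, had 6. SOX9, a transcription factor gene, and FGGY had 5 each. FGGY also had 2 MR49F-only regions, and PPP3CA and ATP2C2 had 1 each. CDK8, the Mediator kinase gene, ANXA3 and PPP2R2A, a regulatory subunit of protein phosphatase PP2A, had 4 LNCaP-only regions each. The cut at 8 genes fell within a tie at 4 regions, which was broken by gene symbol. CDK8 carried 8 BRG1 and 7 SMARCC2 peaks in LNCaP against 1 and 3 in MR49F. In the 10 Mb windows that hold these genes, local background relative to autosomes was lower in MR49F than in LNCaP around TBL1XR1 (ratio 0.797 with BRG1 and 0.821 with SMARCC2), PPP3CA (0.863 and 0.858), ATP2C2 (0.499 and 0.554) and CDK8 (0.862 and 0.908). Around SOX9, FGGY, ANXA3 and PPP2R2A the ratio lay between 0.955 and 1.13. The order of these genes depended on how sites were matched and assigned to genes. When summits within 200 bp defined it, TBL1XR1 had 1 more MR49F-only than LNCaP-only region, and with assignment within 10 kb FGGY did too.

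The classes of regions differed in where they lay relative to genes. For BRG1, 25.1% (24.5 to 25.6) of regions in both lines, 18.7% (18.1 to 19.2) of MR49F-only regions and 9.61% (9.09 to 10.2) of LNCaP-only regions lay within 1 kb of an end of a protein-coding gene. For SMARCC2 the shares were 21.4% (20.8 to 22), 17.4% (16.9 to 17.8) and 11.4% (10.6 to 12.2). Uniform positions gave 2.57%. Whole peak lists, placed by summit, differed less between lines. Near gene ends lay 20.2% of LNCaP and 22.5% of MR49F BRG1 peaks, and 19.4% of SMARCC2 peaks in each line. The contrast between single-line classes therefore does not show a shift of SMARCC2 towards gene ends. The share elsewhere inside genes was 53.5% for LNCaP-only and 44.3% for MR49F-only BRG1 regions, and 55.0% and 45.0% for SMARCC2. Between genes lay 36.9% of LNCaP-only and 37.0% of MR49F-only BRG1 regions, and 33.6% (32.4 to 34.8) and 37.6% (37.1 to 38.2) of SMARCC2 regions.

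Of the 18 gene lists, the neuroendocrine list stood in the top 2.5% of matched random lists with both antibodies. Its genes had 35 BRG1 peaks in MR49F and 15 in LNCaP, an MR49F share of 70.0% (percentile 99.5), and 40 SMARCC2 peaks in MR49F and 11 in LNCaP, a share of 78.4% (percentile 99.1). Of its 22 genes, 11 had more MR49F peaks with both antibodies and 0 had more LNCaP peaks. Over all 20037 genes these counts were 5352 and 756, and for the 21 Wnt genes 12 and 1. A split of this kind is thus not particular to the neuroendocrine list. The 11 genes included NCAM1, a neural cell adhesion molecule gene, and FOXA2, a transcription factor gene, each with 2 MR49F-only regions. SCG3, a secretogranin gene, had 1 region of each kind. The list's position was lost under each of 4 other settings. Its percentiles were 99.1 and 90.1 for BRG1 and SMARCC2 with assignment within 10 kb, 87.1 and 90.7 with extended gene spans, 95.6 and 92.7 with a −log10 q-value of 5 or more, and 84.5 and 92.4 with the 10000 strongest peaks.

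**Figure D3:**
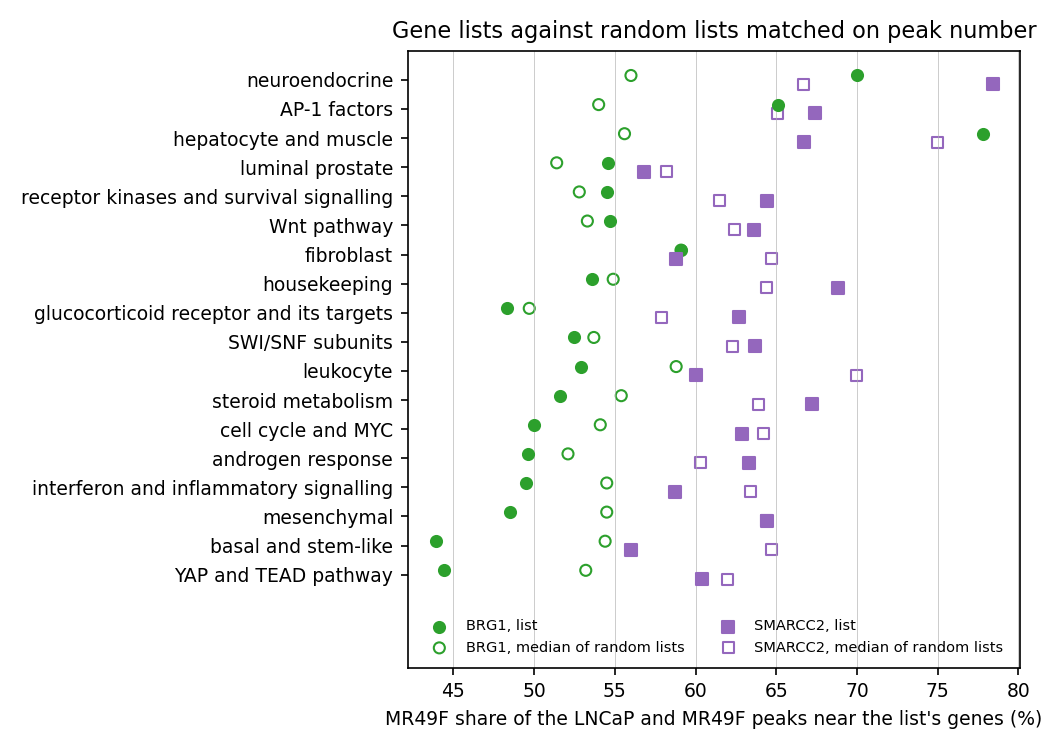
Filled points give the MR49F share of peaks (x axis, percent) near the genes of each list (y axis) for BRG1 (green circles) and SMARCC2 (purple squares), and open points the median of 10000 random lists matched on peak number. The neuroendocrine list, at 70.0% and 78.4%, lies to the right of its random medians of 56.0% and 66.7% with both antibodies.

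AP-1 genes encode dimeric stress-responsive transcription factors, and their list was high with BRG1 (65.1%, percentile 99.0) but not with SMARCC2 (67.4%, percentile 64.9). FOS had 0 peaks in LNCaP, 8 BRG1 and 5 SMARCC2 peaks in MR49F, and 5 MR49F-only regions. FOSB had 2 such regions and also 0 peaks in LNCaP, while JUN and BATF3 had 1 LNCaP-only region each. The BRG1 percentile of the AP-1 list was 98.3 with assignment within 10 kb, but 82.6 with extended gene spans, 95.4 with a −log10 q-value of 5 or more and 40.2 (share 47.1%) with the 10000 strongest peaks. The basal and stem-like list was low with BRG1 (43.9%, percentile 1.68) and at percentile 3.7 with SMARCC2 (56.0%), and its BRG1 percentile lay between 0.065 and 1.47 in other settings except for the 10000 strongest peaks, where it was 11.3. In it SOX9 had 5 and BMI1 1 LNCaP-only regions, and CD44 and PROM1 had 2 MR49F-only regions each. The YAP and TEAD list was low with BRG1 (44.4%, percentile 0.865) and at percentile 33.2 with SMARCC2 (60.4%). Its BRG1 percentile was 0.565 with extended gene spans, but 8.27 with assignment within 10 kb, 6.3 with a −log10 q-value of 5 or more and 22.9 with the 10000 strongest peaks. Its LATS2 had 2 and AMOTL2 1 MR49F-only regions, and PTPN14 had 2 and ANKRD1 1 LNCaP-only regions, PTPN14 beside 1 MR49F-only region.

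Androgen response genes gave an MR49F share of 49.6% with BRG1 (percentile 11.3) and 63.3% with SMARCC2 (percentile 92.0). Among the 10000 strongest peaks of each list, the BRG1 share moved to 54.1% (percentile 93.6) and the SMARCC2 percentile to 97.0, and with assignment within 10 kb the BRG1 percentile was 3.35. Of 31 matched genes, 12 had more MR49F peaks with both antibodies and 4 more LNCaP peaks, and the list held 76 regions in all 4 lists. PMEPA1 and ADAM7 had 5 MR49F-only regions each, and BMPR1B and KCNN2 had 2 LNCaP-only regions each, KCNN2 beside 2 MR49F-only regions. KLK3, which encodes prostate-specific antigen, had 0 regions in a single line by both antibodies. TMPRSS2, an androgen-induced protease gene, had 3 MR49F-only regions, as did FKBP5, an androgen and glucocorticoid target, which had 3 BRG1 and 2 SMARCC2 peaks in LNCaP and 8 and 10 in MR49F. TMPRSS2 had 0 such regions when extended gene spans were used, and FKBP5 had 4. The luminal prostate list lay at 54.6% (percentile 83.8) and 56.8% (percentile 34.3). In that list ELF3, an epithelial transcription factor gene, had 3 MR49F-only regions, whereas STEAP2 had 2 and CDH1, the E-cadherin gene, 1 LNCaP-only regions. The glucocorticoid receptor list lay at 48.3% (percentile 36.8) and 62.7% (percentile 77.3). KLF9 and TSC22D3, both glucocorticoid-induced, had 4 MR49F-only regions each, with TSC22D3 on chromosome X. TIPARP had 2 LNCaP-only regions, and SGK1 had 1 of each kind. With the 10000 strongest peaks, this list lay at percentile 98.6 with SMARCC2 and at the limit of the top 2.5% of random lists with BRG1. By the rule for both antibodies it was counted as high in that setting, where the neuroendocrine list was not.

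Signalling and metabolic lists lay between percentile 6.91 and 80.4 when every peak was assigned within 100 kb, and 2 of them entered the top or bottom 2.5% with a single antibody in other settings, as given beside them. The Wnt list was at 54.7% (percentile 67.7) with BRG1 and 63.6% (percentile 64.2) with SMARCC2, where it came to percentile 1.91 with the 10000 strongest peaks. In it ZNRF3 had 4 and APCDD1 2 MR49F-only regions (4 and 0 with extended gene spans), and RNF43 and TCF7L2 had 1 LNCaP-only region each. Receptor kinases and survival signalling lay at 54.5% (percentile 73.3) and 64.4% (percentile 80.4). With extended gene spans this list reached percentile 99.1 with BRG1 and 94.8 with SMARCC2, and with the 10000 strongest peaks 99.4 and 88.2. It had 4 MR49F-only regions and 1 LNCaP-only region at BCL2, an anti-apoptotic gene, and 1 LNCaP-only region each at MCL1 and FGFR2. The interferon and inflammatory list lay at 49.5% (percentile 8.57) and 58.7% (percentile 10.2). IL6ST, the shared receptor subunit of the interleukin 6 family, had 4 MR49F-only regions and 0 peaks in LNCaP, TNFAIP3 had 2 LNCaP-only and 1 MR49F-only region, and IL6 had 1 LNCaP-only region. The mesenchymal list lay at 48.5% (percentile 6.91) and 64.4% (percentile 51.2). FN1, the fibronectin gene, had 2 and TNC 3 MR49F-only regions, while ZEB2 had 2 LNCaP-only regions and TGFBR2 1 of each kind. Cell cycle and MYC genes lay at 50.0% (percentile 14.6) and 62.9% (percentile 38.3). CDKN1A, the gene of the cell cycle inhibitor p21, had 3 MR49F-only regions and 0 peaks in LNCaP, CCNE1 had 2 MR49F-only regions and 1 LNCaP-only region, and CDK1 and CDK6 had 1 LNCaP-only region each. Steroid metabolism genes lay at 51.6% (percentile 22.2) and 67.2% (percentile 74.3), with 1 MR49F-only region each at CYP11A1 and HSD17B4 and 1 LNCaP-only region at AKR1C2. Limiting each list to its 10000 strongest peaks moved the BRG1 percentile to 93.7 for the interferon and inflammatory list, 89.7 for cell cycle and MYC genes and 92.5 for steroid metabolism genes, and the SMARCC2 percentile to 7.87 for steroid metabolism and 4.51 for mesenchymal genes.

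SWI/SNF subunit genes lay at 52.5% (percentile 35.9) with BRG1 and 63.7% (percentile 64.4) with SMARCC2. SMARCA4 and SMARCC2, whose products were precipitated, had 0 regions in a single line by both antibodies. BICRA had 3 and ARID1B 2 MR49F-only regions, SMARCA2 had 3 LNCaP-only and 2 MR49F-only regions, and ARID2 had 1 LNCaP-only region. Housekeeping genes lay at 53.6% (percentile 38.1) and 68.8% (percentile 77.8), the latter at percentile 1.51 with the 10000 strongest peaks, with 4 MR49F-only regions at YWHAZ (0 with extended gene spans) and 1 at HPRT1, on chromosome X. The lists for other cell types rested on few peaks. Fibroblast genes lay at 59.1% (percentile 60.2) and 58.8% (percentile 16.5), with 1 MR49F-only region at FAP and 1 LNCaP-only region at PDGFRA. Leukocyte genes lay at 52.9% (percentile 29.4) and 60.0% (percentile 20.5), with 1 MR49F-only region at PTPRC and 1 LNCaP-only region at CD8A. Hepatocyte and muscle genes lay at 77.8% (percentile 91.3) and 66.7% (percentile 24.3), with 2 MR49F-only regions at ALB, 1 at APOA1 and 1 LNCaP-only region at FGB.

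Chromosomes differed in the ratio of MR49F to LNCaP peaks. Chromosome X had 583 BRG1 peaks in LNCaP and 1466 in MR49F, a ratio of 2.51, and 389 SMARCC2 peaks in LNCaP and 1678 in MR49F, a ratio of 4.31. It held 666 MR49F-only and 10 LNCaP-only regions of both antibodies. Among autosomes, chromosome 18 had the highest ratios, 1.67 for BRG1 and 2.6 for SMARCC2. The lowest BRG1 ratio was 1.01 on chromosome 3, and the lowest SMARCC2 ratio was 1.51 on chromosome 21. On chromosomes 1 to 22 alone, both antibodies called 11302 MR49F-only and 2381 LNCaP-only regions.

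**Figure D4:**
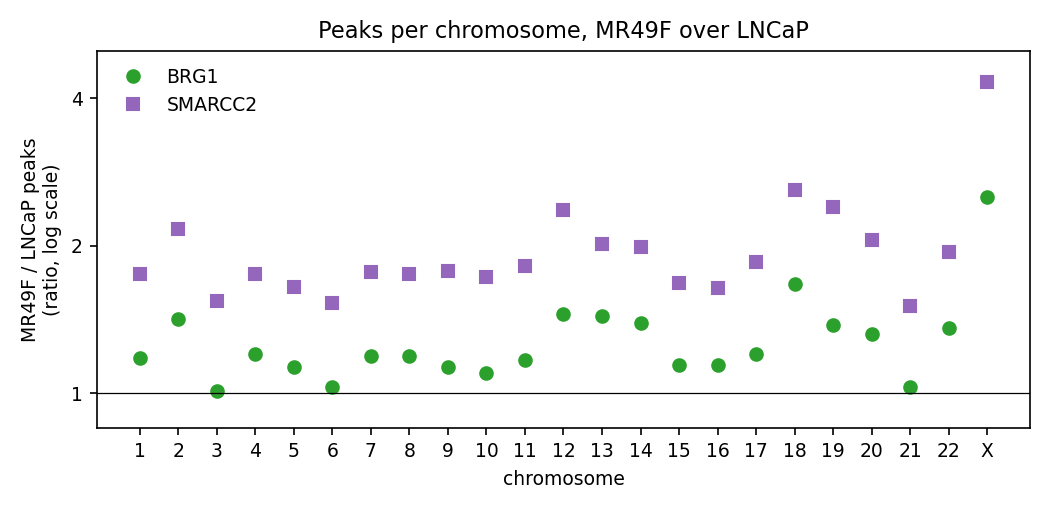
Points give the ratio of MR49F to LNCaP peaks (y axis, log scale) on each chromosome (x axis) for BRG1 (green circles) and SMARCC2 (purple squares), with a line at a ratio of 1. Chromosome X stands highest at 2.51 and 4.31, and the autosomes lie between 1.01 and 1.67 for BRG1 and between 1.51 and 2.6 for SMARCC2.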

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

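The tests of sequencing depth, and the test of weak peaks for SMARCC2 alone, were chosen after the results were seen. The other tests and their limits were set before their outcome was known.

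SMARCC2 peaks were fewer than BRG1 peaks in LNCaP (ratio 0.711) and more numerous in MR49F (ratio 1.07), so the antibodies ranked in opposite order in the lines. This stood out because the ratio lay on opposite sides of 1, and the difference was not tested, since each value comes from 1 pair of libraries. Deeper sequencing of SMARCC2 in MR49F is argued against by the recovered depth, whose SMARCC2 to BRG1 ratio in MR49F was 0.856 times that in LNCaP. Lower sensitivity of the LNCaP SMARCC2 library may account for it: SMARCC2 was found at the strongest 10% of BRG1 peaks 2.85 percentage points more often in MR49F than in LNCaP, and at the weakest 10% 15.3 points more often, with a wider gap between these ends (54.9% in LNCaP and 90.7% in MR49F in step 5 of 10). A gap below 5 points among strong peaks with 20 or more among weak peaks had been set as the sign of it, so this cannot be told apart from a different balance of the subunits in MR49F.

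Both antibodies gave more peaks in MR49F than in LNCaP. Deeper sequencing is argued against, because recovered depth in MR49F was 0.81 times that in LNCaP for BRG1 and 0.695 times for SMARCC2. Copy number differences as the whole source are argued against as well, since MR49F still had 1.18 times as many BRG1 peaks and 1.78 times as many SMARCC2 peaks in the 135 of 285 windows of 10 Mb whose background differed by under 10% between lines. Windows at the caller's lowest background in both lines count as alike, though copy number cannot be compared there. For weak peaks passing the caller's threshold only in MR49F, a value against it had been set. It was at least 20% of the strongest 10% without a LNCaP peak, with both antibodies. BRG1 gave 19.8% (18.6 to 21), so the joint test leaves it open. SMARCC2 alone gave 26.1% (24.9 to 27.3), but its limit was chosen after that value was seen. A less sensitive LNCaP SMARCC2 library, left open above, could also leave strong sites below the threshold. SMARCC2 alone therefore does not decide it. Median fold enrichment was 4.79 with BRG1 and 5.27 with SMARCC2 in MR49F, against 4.05 and 4.22 in LNCaP. A −log10 q-value of 5 or more was reached by 79.3% and 84.1% of MR49F peaks, against 68.5% and 70.4% in LNCaP. More efficient precipitation in MR49F could give such values, and so could stronger occupancy, so they do not decide between these. Differences in precipitation efficiency between single libraries, the line and the enzalutamide in the medium all stay open and untested.

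On chromosome X, MR49F had 2.51 times the BRG1 and 4.31 times the SMARCC2 peaks of LNCaP. Local background on X relative to autosomes was 1.33 times higher in MR49F with BRG1 and 1.35 times with SMARCC2, which passes the limit of 1.3 set for more copies of X and is consistent with them. Among LNCaP BRG1 and SMARCC2 peaks on X, 59.1% and 61.5% sat at the lowest background the caller uses, so the true ratio of backgrounds may be higher. Across 285 windows of 10 Mb, which are not independent replicates, background ratio and log peak ratio were positively correlated (Pearson's r 0.402 with BRG1 and 0.45 with SMARCC2, Spearman's coefficient 0.312 and 0.321), though chromosome 19 had a background ratio of 0.76 and a BRG1 peak ratio of 1.38. A biological difference of X between the lines was not tested.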

How the results depend on the processing

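Leaving out list genes on chromosome X was chosen after seeing the data, and it left 1 list high, the neuroendocrine list, at percentiles 98.6 and 98.5. The 2 motif alternatives were not run. MR49F-only regions outnumbered LNCaP-only regions in every setting run, for each antibody and for both. For a single antibody the longer MR49F list largely fixes this order, whatever the rule for matching sites. A change of that rule therefore does not test it. The count for both antibodies comes from the same lists and also depends on their lengths, so it is not separate support for the order. Where lists were cut to equal length, the counts for a single antibody were close to even, which equal length largely imposes. A −log10 q-value limit cannot tell weak occupancy from none, and 1 library per group limits every value. The cause was not tested for the moves below, except where a list was shortened.

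With 50% reciprocal overlap, BRG1 gave 15011 regions in both lines and 21163 in LNCaP only (log2 ratio of MR49F-only to LNCaP-only 0.47, against 0.80), and SMARCC2 gave 12725 and 12981 (1.43, against 2.27). For both antibodies the log2 ratio was 2.05, against 2.32. Overlap with the other antibody was 40.0% for LNCaP BRG1, 56.3% for LNCaP SMARCC2, 65.2% for MR49F BRG1 and 60.6% for MR49F SMARCC2. With summits within 200 bp, LNCaP-only regions were 20168 for BRG1 (log2 ratio 0.49) and 10928 for SMARCC2 (1.59), with 2.15 for both antibodies, and the overlaps were 39.4%, 55.4%, 62.4% and 58.1% in the same order. With a −log10 q-value of 5 or more in every list, the log2 ratios were 1.22, 2.73 and 2.80, and overlaps were 76.9% for LNCaP SMARCC2, 82.5% for MR49F BRG1 and 73.7% for MR49F SMARCC2. With that limit in the counted line only, LNCaP-only regions were 6234 for BRG1 and 3141 for SMARCC2, the log2 ratios 1.21, 2.82 and 2.45, and the overlaps 67.6%, 86.0%, 88.6% and 80.7%. On chromosomes 1 to 22 the log2 ratios were 0.74, 2.21 and 2.25.

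With the 10000 strongest peaks of each list, which fixes the list lengths, BRG1 gave 4344 regions in both lines, 5569 in LNCaP only and 5629 in MR49F only, and SMARCC2 gave 4592 in both and 5401 in MR49F only. The log2 ratio was 0.02 for each antibody and 0.33 for both, with 2876 MR49F-only regions. Overlaps were 62.9%, 63.8%, 71.6% and 72.0%.

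Near gene ends widened to 2.5 kb lay 14.4% of LNCaP-only and 24.1% of MR49F-only BRG1 regions, and 15.8% and 22.4% for SMARCC2. With a −log10 q-value of 5 or more, the BRG1 shares were 11.8% and 21.8%, and that of MR49F-only SMARCC2 regions 18.8%. The number of lists high with both antibodies was 0 with assignment within 10 kb, 0 with extended gene spans and 0 with the −log10 q-value limit. With each peak list cut to its strongest peaks, the glucocorticoid receptor list was high with both antibodies, though only at the limit with BRG1. The neuroendocrine list was not high in that setting.

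For single genes, MR49F-only minus LNCaP-only regions of both antibodies changed sign in 20 cases, among them TBL1XR1, with 8 LNCaP-only and 0 MR49F-only regions when sites sharing 1 bp were joined. With reciprocal overlap it was 1 at JUN, CDH1 and STEAP2. With summits within 200 bp it was 1 at PTPN14, BMI1, TBL1XR1 and TNFAIP3. With the −log10 q-value limit it was 1 at TNFAIP3, IL6 and SMARCA2 and -1 at ARID1B. With the 10000 strongest peaks it was 1 at PTPN14 and IL6, -1 at ZNRF3, HSD17B4, ZNF277, EFR3A and TNC, and -2 at ARID1B. With assignment within 10 kb it was 1 at FGGY. Of 83 genes where it was not 0 at first, it came to 0 at 39 with the 10000 strongest peaks, 35 with assignment within 10 kb, 19 with a −log10 q-value of 5 or more in every list, 11 with extended gene spans, 10 with summits within 200 bp, 7 with the limit in the counted line only and 6 with reciprocal overlap.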

Other observations

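The windows, peaks and genes in this part are those with the highest counts or widths, chosen after their values were seen, and no test against the density of genes or peaks was made. On chromosome 2, the window from 150000001 to 151000000, whose only protein-coding gene is RND3, held 20 MR49F-only regions among 40 regions, with 1 LNCaP-only region. On chromosome 15, the window from 98000001 to 99000000 around IGF1R held 18 MR49F-only regions among 56, and 0 LNCaP-only regions. On chromosome 12, the window from 53000001 to 54000000, which reaches HOXC10 to HOXC13 and holds RARG, a retinoic acid receptor gene, held 20 among 72, with 2 LNCaP-only regions. On chromosome X, the window from 154000001 to 155000000 held 20 among 43, with 0 LNCaP-only regions. LNCaP-only regions were densest on chromosome 21 from 21000001 to 22000000, where NCAM2, a neural cell adhesion gene, is the only protein-coding gene. That window held 15 LNCaP-only regions and 1 MR49F-only region among 49. The next was on chromosome 3 from 175000001 to 176000000, overlapping NAALADL2, with 13 LNCaP-only regions and 1 MR49F-only region among 57. In the 10 Mb windows that hold these places, the ratio of MR49F to LNCaP background was 0.859 with BRG1 and 0.851 with SMARCC2 around NCAM2, 0.797 and 0.821 at NAALADL2, 1.24 and 1.35 around RARG, and between 0.995 and 1.09 around RND3 and IGF1R. On the whole of chromosome X it was 1.33 and 1.35.

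The widest peak of any list was an MR49F BRG1 peak of 30.6 kb on chromosome 19 from 12996081 to 13026655, nearest to an end of NFIX, a nuclear factor I gene. The widest MR49F SMARCC2 peak spanned 18.3 kb on chromosome 11 from 34624694 to 34642960 at EHF, an epithelial ETS transcription factor gene. In LNCaP the widest BRG1 peak was 13.8 kb, on chromosome 14 from 29798161 to 29812009 with no protein-coding gene end within 100 kb, and the widest SMARCC2 peak was 6.12 kb, on chromosome 11 from 114128231 to 114134353 at ZBTB16, a zinc finger gene.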
